A study of Mus musculus with 3 samples.

How the data were processed

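Skeletal muscle RNA of 12-week-old mice was measured in 3 libraries, 1 each of wild type, heterozygous and homozygous for the Rbm20 knock-in. Libraries were made with a low-input SMART-seq kit and Nextera XT and run on an Illumina NovaSeq, per the labels' protocols. The labels also name other ages, which were not analysed here. The muscle each library came from is not given in the sources used here.

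The deposited table holds, for each exonic part, raw counts of inclusion and exclusion reads, a PSI fraction per library, its difference from wild type, and the length of the part in bases, per the file headers. The submitters' processing notes name cutadapt 1.1, Trimmomatic 0.32, TopHat2 2.0.14, Bowtie 1.1.1 and the build GRCm38, without saying what each was used for. The program that counted exonic parts and the annotation release it used are not given in the sources used here. From the values, each deposited PSI fraction equals inclusion reads divided by the part length plus 131, over that value plus exclusion reads divided by 131, within 5e-07. The deposited difference is wild type minus the other genotype, per the file headers; here every difference is the named genotype minus the other, in percentage points of PSI. No other per-sample columns were present.

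An exonic part is a stretch of exon between neighbouring exon boundaries, so an exon can be several parts, and skipping one exon set moves many parts. Genes that overlap were merged in the table; 1405 such merged groups hold 40250 parts and 9.57%, 9.67% and 8.12% of inclusion reads in wild type, heterozygous and homozygous muscle. They entered the counts over all parts but are not named, and list members inside them have no value. Reads shared by near-identical genes or exons could be split by the authors' processing, so genes of such families are called uncertain. Parts were placed in exons, coding sequence or untranslated regions with GENCODE M21 on GRCm38, the build of the table. Ttn exon numbers and residues come from ENSMUST00000099981.8, its longest coding transcript there.

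A part was called different when PSI differed by at least 20 percentage points and inclusion plus exclusion reads were at least 10 in both libraries. There is no test between genotypes. The 95% interval of a PSI is the Wilson interval of the inclusion share of reads carried to the PSI scale, and that of a difference is Newcombe's. These cover counting error only, since reads lack molecular identifiers. Levels are RPM, a gene's inclusion reads per 1000000 inclusion reads of its library, with log2 ratios on the value plus 1 and genes measured at 5 or more RPM in at least 1 library.

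Before the data were examined, these were fixed: the rule above, the pairs of libraries, the 7 splicing lists and 12 marker lists, the named genes and the alternatives. Named genes are Rbm20 and Ttn, the 15 genes furthest apart in homozygous against wild type and the 10 in heterozygous against wild type, ranked by the Newcombe bound nearest 0 with 1 part per gene, and in each splicing list the 4 highest ranked in homozygous against wild type; some genes that the rule names are not reported here. A list's value is the median over its genes of the largest difference per gene, given as a percentile of 10000 random gene lists of the same size, matched on the number of measured parts (10 bins) and mean coverage (3 bins). Marker lists were set against random lists matched on expression. Such percentiles describe these libraries, not the genotypes.

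Counting error was simulated 20 times with binomial draws at the real depths from the inclusion share of reads pooled over the 3 libraries. The rule, intervals and list percentile were tested on simulated data with 200 parts moved. For homozygous against wild type, over 204571 parts, the rule recovered 96.0% of parts moved by 30 points and 99.0% of those moved by 50, and called 0.514% of the others.

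The settings varied by plan were 10 or 30 points, 20 reads or no minimum, the size rule with Fisher's exact test on the reads at a Benjamini-Hochberg level of 0.05, 1 part per gene, touching parts merged, and parts with PSI of 0 or 100% left out. Fisher's test there compares the reads of 2 libraries, not the genotypes. After the data were seen, these were added: at least 100 reads, a supported junction (exclusion reads per base at least 5% of the 90th percentile of the gene's inclusion reads per base), overlapping genes left out, and parts with the same exclusion counts taken as 1. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.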

Results

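RNA of skeletal muscle was sequenced from 12-week-old mice that carry the Rbm20 missense change I538T, placed in the gene with CRISPR/Cas, in 0, 1 or both copies. RBM20 is an RNA-binding protein that controls the splicing of Ttn, the gene of the giant sarcomere protein titin, in heart and skeletal muscle. The mouse change stands for the human change I536T, per the labels. There were 3 libraries, 1 each of wild type, heterozygous and homozygous mice. The values were inclusion and exclusion read counts and PSI (percent spliced in, the share of a gene's transcripts that hold a given exonic part) for 469293 exonic parts. Inclusion reads summed to 239837797 in wild type, 265358773 in heterozygous and 215923385 in homozygous muscle, and exclusion reads to 53925304, 58640621 and 51998453; a read can count in several parts. Parts with at least 10 reads numbered 246072, 249216 and 229562, and their median depth was 94, 113 and 84 reads. With 1 library per genotype, no difference below has a replicate check, so no p-value is given between genotypes. Differences describe these libraries, and 95% intervals cover counting error only, because PCR copies of a molecule are counted as separate reads.

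The targeted gene Rbm20 (ENSMUSG00000043639, chromosome 19, GRCm38) had 13.0 RPM (inclusion reads scaled to the library's total, in parts per 1000000) in wild type, 10.8 in heterozygous and 2.97 in homozygous muscle, from 3110, 2866 and 641 reads. Several of its coding parts had no reads in the homozygous library. The coding part at 53843223 to 53843844 held 177, 307 and 0 inclusion reads, and the last untranslated part, at 53865381 to 53867080, held 1350, 609 and 436. A part annotated as untranslated region, 139 bases long at 53793308 to 53793446, had a PSI of 53.8% (36.1 to 70.6) in wild type and 12.6% (7.43 to 20.7) in heterozygous muscle, with no reads in the homozygous library. The counts do not show which allele a read came from, so they do not check the genotype labels.

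The first comparison asked which exons differ in PSI between homozygous and wild-type muscle, with Ttn looked at first as the best known target of RBM20. In Ttn (ENSMUSG00000051747, chromosome 2, minus strand), 23 of 392 measured parts differed by at least 20 percentage points, 15 higher and 8 lower in the homozygous library. All 15 higher parts lay between 76827483 and 76849071, in exons 138 to 191 of a 347-exon transcript. Their 548 coded residues were 76.8% proline, glutamate, valine or lysine, against 35.1% over the whole protein, which places them in the elastic PEVK region of titin. Their mean PSI was 37.8% in wild type, 33.0% in heterozygous and 61.8% in homozygous muscle. Exon 191 (76827483 to 76827560) had the largest of these differences, 23.4% in wild type and 50.2% in homozygous muscle, a difference of 26.8 points (25.03 to 28.56). Of the 8 lower parts, 7 rested on at most 150 exclusion reads in each library. The other, at 76935924 to 76936381, an exon of non-coding transcripts, was at 51.6% in wild type, 26.0% in heterozygous and 25.9% in homozygous muscle. No Ttn part differed by 30 points or more in this pair.

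**Figure D1:**
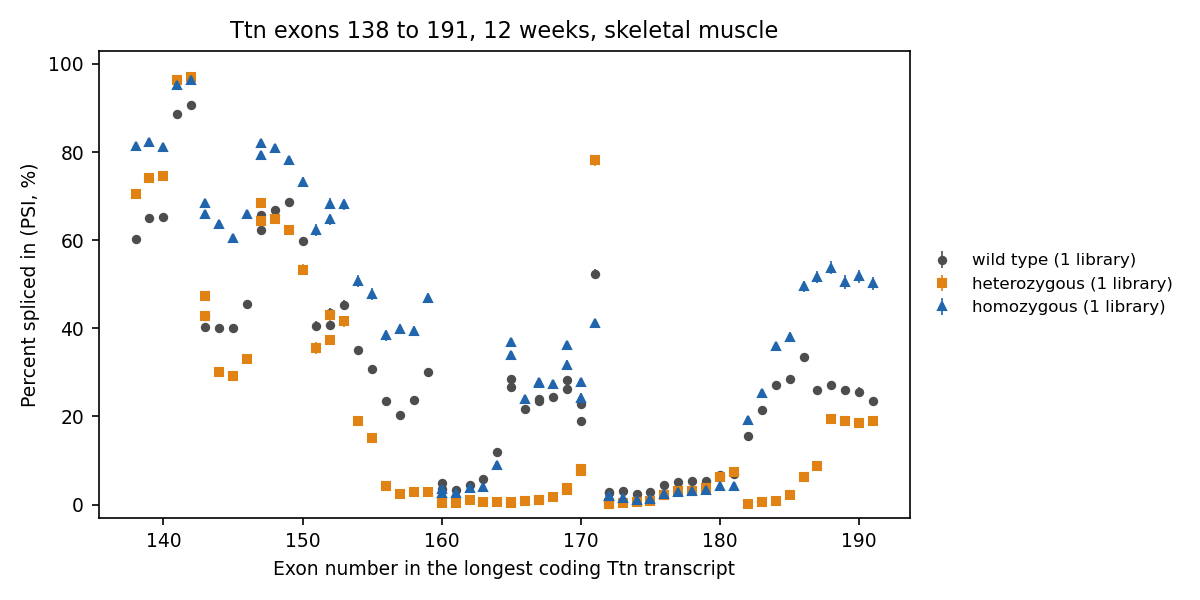
PSI in percent (vertical axis) of the exonic parts in Ttn exons 138 to 191 (horizontal axis, exon number) in the wild-type, heterozygous and homozygous libraries, 1 library each; bars are 95% Wilson intervals and are mostly smaller than the symbols. At exon 191 the homozygous library sits at 50.2% and wild type at 23.4%, while the heterozygous library is the lowest of the 3 in much of the stretch.

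Over all genes, 11401 of 204571 parts measured in both libraries (5.57%) differed between homozygous and wild-type muscle, 5387 higher and 6014 lower, in 4476 named genes. Counting error alone gave a mean of 1172 such parts in 20 simulations at the same depths. Of the 11401 parts, 56.4% had a PSI of exactly 0 or 100% in a library, and the median depth of the shallower library was 35 reads. With at least 100 reads in both libraries, 2069 parts differed.

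The largest differences were in genes of many functions. Atp1a4, a sodium pump subunit best known from sperm, had a coding exon (chromosome 1, 172233953 to 172234121) at 0% in wild type and 100% in both the heterozygous and homozygous libraries. Mpc1, a subunit of the mitochondrial pyruvate carrier, had a part (chromosome 17, 8293419 to 8293495) at 1.49% in wild type, 0.884% in heterozygous and 100% in homozygous muscle. Its inclusion reads were 401, 286 and 348, and its exclusion reads 16686, 20194 and 0, so the difference rests on exclusion reads that were absent from the homozygous library. Cdk5rap1, which modifies mitochondrial transfer RNA, had a coding exon at 0% in wild type from 26 reads and at 100% in both other libraries. Zfp638, Letm2 and Zranb3 had a part at 0% in wild type and 100% in homozygous muscle, from 14, 32 and 18 exclusion reads in wild type. Lrrc45, Tmem87b, Wdr12 and Sel1l2 had a part at 100% in wild type and 0% in homozygous muscle, that of Lrrc45 in non-coding transcripts. Retnlg, a neutrophil gene, was at 0% in wild type, 6.59% in heterozygous and 100% in homozygous muscle. Serpinb6c, Mup13, Mup14 and Ces1e also ranked among the 15 largest, but belong to families with near-identical copies, and their values are uncertain because reads can be split between the copies.

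Among genes known as RBM20 targets in heart, 25 of 33 measured genes had a part that differed between homozygous and wild-type muscle, 8 with higher parts only, 6 with lower parts only and 11 with both. Slmap, which codes a sarcolemma-associated protein, had a coding exon (chromosome 14, 26429788 to 26429910) at 0% in wild type and heterozygous and 81.9% (70.5 to 89.6) in homozygous muscle. Git2 had a part of non-coding transcripts at 0%, 16.9% and 100% in the 3 libraries. Lmo7, a cytoskeletal adaptor, had a coding exon at 31.2% in wild type and 100% in both knock-in libraries. Myh7, the slow myosin heavy chain, had an untranslated part at 6.14%, 4.18% and 100%, from 11 reads in the homozygous library, where the gene itself was scarce. The median over the list of each gene's largest difference was 40.1 points, against a median of 19.5 for matched random lists, the 99.99th percentile of 10000. In the other pairs the list was at a percentile of 99.8 in heterozygous against wild type and 99.7 in homozygous against heterozygous. Counting only parts with a supported junction (exclusion reads per base at least 5% of the gene's level in 1 of the libraries), a setting chosen after seeing the data, the percentiles were 99.92 in homozygous against wild type, 97.1 in heterozygous against wild type and 96.1 in homozygous against heterozygous.

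Structural genes of the costamere and cytoskeleton were also far out, with 35 of 47 measured genes holding a part that differed, 10 higher only, 14 lower only and 11 both, at a percentile of 100. Clasp2, a microtubule plus-end protein, had a part of non-coding transcripts at 100% in wild type, 78.8% in heterozygous and 20.04% in homozygous muscle. Macf1 had a coding exon at 12.3%, 100% and 100%. Dtnb had a coding exon at 0% (0 to 24.9) from 10 reads, 46.3% (24.0 to 70.2) and 100% (85.4 to 100). This list was at a percentile of 99.6 in heterozygous against wild type and 100 in homozygous against heterozygous.

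In the sarcomere and Z-disc list, 19 of 60 measured genes had a part that differed, 7 higher only, 6 lower only and 6 both. Neb, the gene of the thin filament ruler nebulin, had a coding exon (chromosome 2, 52308686 to 52308790) at 100% in wild type and heterozygous and 47.9% (45.6 to 50.1) in homozygous muscle. Its inclusion reads were 1310, 1485 and 1217, and its exclusion reads 0, 0 and 736, so the difference rests on exclusion reads seen only in the homozygous library. Mybpc2, the fast myosin-binding protein C, had a coding exon (chromosome 7, 44516383 to 44516515) at 51.1%, 91.1% and 99.9%. The list's median largest difference was 6.11 points, at the 4.75th percentile of random lists, while the number of genes with a part that differed, 19 against a random median of 16, was at a percentile of 82.4. With at least 100 reads and a supported junction, settings chosen after seeing the data, the median was 3.42 points at a percentile of 50.8.

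Of 34 measured genes of excitation-contraction coupling and calcium handling, 13 had a part that differed, 6 higher only, 4 lower only and 3 both, with a median largest difference of 11.9 points at a percentile of 73.4. Counting only parts with a supported junction, the median was 4.73 points at a percentile of 2.61. With at least 100 reads as well, it was 3.63 points at a percentile of 60.4. Srl, which codes sarcalumenin, had a 3-base coding part at 52.8% in wild type, 93.7% in heterozygous and 96.8% in homozygous muscle. Stim1, the store calcium sensor, had a part of non-coding transcripts at 39.5% in wild type and 0% in both other libraries. Cacnb1 had a part at 50.9%, 100% and 100%, and Asph a coding exon at 100%, 100% and 16.4%, the last from 10 reads. Among genes whose splicing shifts after birth under MBNL and CELF proteins, 16 of 32 had a part that differed, 8 higher only, 6 lower only and 2 both, at a percentile of 82.6. Mbnl1 had an untranslated part at 6.45%, 23.6% and 53.9%, and Nrap a coding exon at 100%, 100% and 61.3%. Ank2 had a part of non-coding transcripts at 1.44%, 100% and 100% (45.1 to 100), and Numa1 an untranslated part at 100%, 0% and 26.6%.

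Of 44 measured splicing regulators, 21 had a part that differed, 12 higher only, 8 lower only and 1 both, at a percentile of 95.1. Rbfox2 had a coding exon at 100% (73.7 to 100), 74.6% (60.4 to 85.0) and 0% (0 to 8.34), from 13 reads in wild type. Its interval for heterozygous minus wild type, -39.6 to 2.87, held 0. Celf2 had a part of non-coding transcripts at 13.7%, 22.3% and 100% (66.9 to 100). Ddx17 had a part at 25.8%, 100% and 100%, and Ptbp3 a coding part at 24.7% (10.9 to 46.6), 68.3% and 90.6%. Of 20 measured genes of glycolysis and glycogen, only Ckm and Gbe1 had a part that differed, both lower, with a median largest difference of 8.67 points at a percentile of 26.7, and 4.05 points at 1.18 with supported junctions only. With at least 100 reads as well, 4.05 points stood at a percentile of 38.1. The number of genes, 2 against a random median of 5, was at a percentile of 3.2. Ckm, the muscle creatine kinase, had an untranslated part at 100%, 100% and 28.9%, with 1341 exclusion reads in the homozygous library and none in the others. Gbe1, the glycogen branching enzyme, had a part of non-coding transcripts at 51.5%, 7.44% and 18.3%.

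The next comparison asked the same of heterozygous against wild-type muscle. In Ttn, 79 of 392 parts differed, 64 higher and 15 lower in the heterozygous library. Of the lower parts, 14 lay in exons 158 to 186 of the PEVK stretch and the other was the non-coding part at 76935924. The 15 had a mean PSI of 28.0% in wild type, 3.63% in heterozygous and 33.7% in homozygous muscle, so the heterozygous and homozygous libraries lay on opposite sides of wild type for most of them. Exon 165 (76833030 to 76833107), for example, was at 26.6%, 0.565% and 33.9%. The higher parts were of another kind. For 63 of the 64, exclusion reads per base stayed under 5% of the gene's level in both libraries, and 59 of these 63 had 0 exclusion reads in the heterozygous library against 37 to 176 in wild type. The wild-type exclusion counts of the 63 took only 6 distinct values, so these parts are not independent. The exception, exon 171 (76831788 to 76831874), was at 52.4% in wild type, 78.1% in heterozygous and 41.2% in homozygous muscle. Counting parts with such a supported junction only, 1 part was higher and 15 were lower.

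Over all genes, 12430 of 215161 measured parts (5.78%) differed between heterozygous and wild-type muscle, 5529 higher and 6901 lower, in 4793 named genes, with 1074 from counting error alone. Atp1a4, Serpinb6c and Cdk5rap1 were among the largest differences in this pair too. Fancl, part of the Fanconi anaemia ubiquitin ligase, had a coding exon (chromosome 11, 26459686 to 26459836) at 100% in wild type, 0% in heterozygous and 100% in homozygous muscle. Slx4ip had a coding exon at 0.671%, 100% and 57.5%. Micall1 had a part of non-coding transcripts at 0% in wild type and 100% in heterozygous muscle, with no reads in the homozygous library. Myh3, the embryonic myosin heavy chain, had a coding exon at 3.77%, 100% and 0%, but shares sequence with other myosin genes, and Ces1f, Il11ra2 and Ighg2c are likewise uncertain because of similar copies. By list, a part differed in 23 of 33 RBM20 heart targets, 30 of 47 costamere genes, 18 of 60 sarcomere genes, 13 of 34 calcium genes, 12 of 32 postnatal splicing genes, 21 of 44 splicing regulators and 2 of 20 glycolysis genes. Matched random lists had medians of 18, 23, 15, 10, 13, 16 and 6 such genes, in the same order. The counts stood at percentiles of 97.4, 99.2, 83.9, 87.2, 34.9, 95.4 and 2.6.

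The 3 libraries were compared as a set to ask whether parts followed the number of mutant copies. Homozygous and heterozygous muscle differed in 11322 of 205179 measured parts, 6065 higher and 5257 lower in homozygous, close to the number that separated either from wild type. In the 15 Ttn parts that were higher in homozygous than in wild type, a set chosen without the heterozygous library, the heterozygous PSI lay below both other libraries in 12 and between the others in 3. It was below wild type beyond counting error in 11 of the 15, and neighbouring parts have similar exclusion counts, so these are not independent. In a comparison added after the data were seen, homozygous and heterozygous muscle differed in 116 of 392 Ttn parts, 34 higher and 82 lower in homozygous. With a supported junction, 34 were higher and 1 was lower. Over all genes, 10192 parts that differed between homozygous and wild type were measured in the heterozygous library, and its PSI lay between the others in 65.2% (Wilson 64.2 to 66.1), ends included. That interval takes each part as independent, which parts of the same gene are not. With 1 part per gene the share was 67.2%. With the libraries exchanged, homozygous lay between the others in 63.7% of the parts that differed between heterozygous and wild type, and wild type lay between in 67.8% of those that differed between homozygous and heterozygous. The share with heterozygous between was therefore not above both exchanges. Parts that differed from wild type in the same direction in both knock-in libraries numbered 4947. Taking heterozygous or homozygous as the shared reference gave 4757 and 4895, close to that number. Independent lists would share 270, and simulations of unchanged libraries against the same wild-type library gave a mean of 240.5, but these hold no differences between animals. The overlap may therefore come from the shared wild-type library, which cannot be split.

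**Figure D2:**
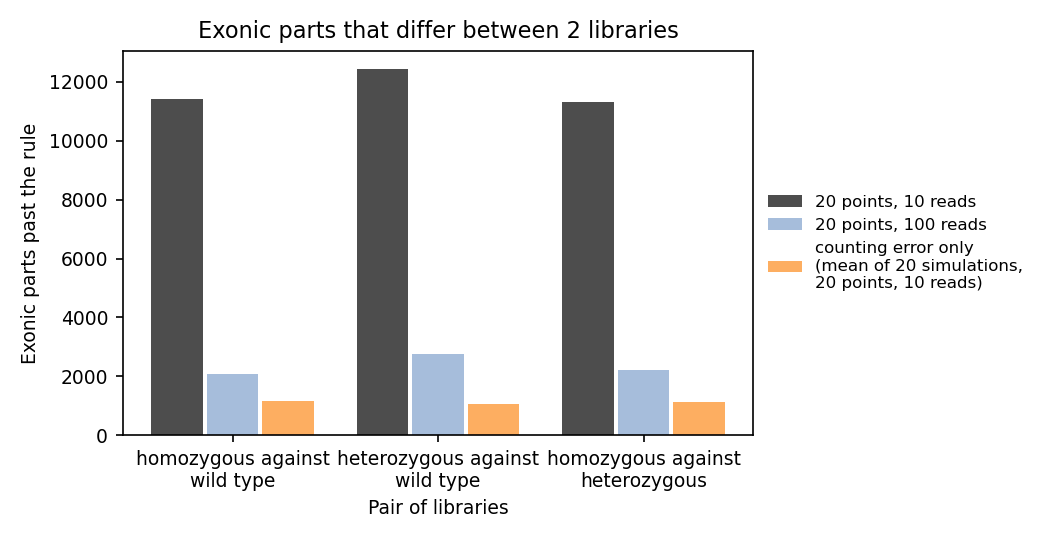
Number of exonic parts (vertical axis) that differ by at least 20 percentage points of PSI in each pair of libraries (horizontal axis), with at least 10 reads, with at least 100 reads, and in simulations of counting error alone (mean of 20). The 3 pairs are alike, with 11401, 12430 and 11322 parts at 10 reads.

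The libraries also differed in reads of fibre-type markers and of markers of other cells. Slow-fibre genes were lower in both knock-in libraries, with 5 of 8 at least 2-fold lower in heterozygous and 7 of 8 in homozygous muscle. Myh7 had 179.7 RPM in wild type, 42.5 in heterozygous and 2.13 in homozygous muscle, and Tnnt1, the slow troponin T, had 555, 163 and 12.1. The list's median log2 ratio to wild type was -1.59 in heterozygous and -4.75 in homozygous muscle, below all 10000 random lists in each, while the median of all 9427 measured genes was 0.10 and -0.18. All 11 fast-fibre genes stayed within 2-fold, with list medians of -0.10 and 0.20, and Myh4, the fast myosin heavy chain, had 13839, 10389 and 15941 RPM. Of the Ttn and other splicing differences above, each was measured in libraries that also differed in these slow-fibre reads.

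**Figure D3:**
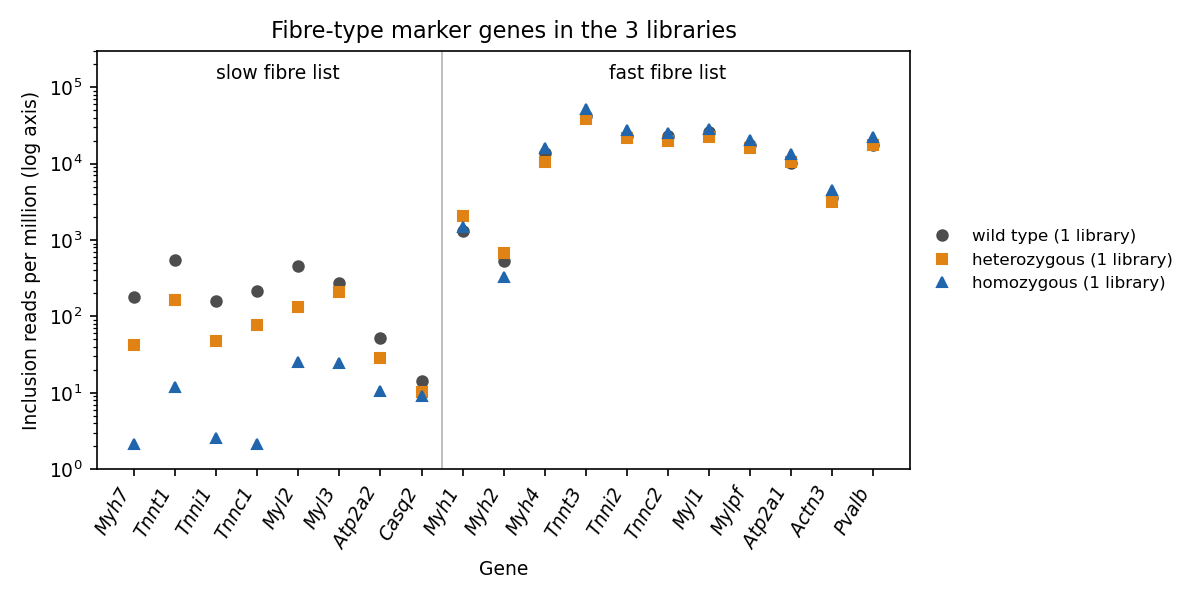
RPM, scaled inclusion reads (vertical axis, log scale), of 8 slow-fibre and 11 fast-fibre genes (horizontal axis) in the wild-type, heterozygous and homozygous libraries, 1 point per library. Myh7 has 179.7 RPM in wild type and 2.13 in homozygous muscle, while the 11 fast-fibre genes lie within 2-fold of wild type.

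Of the marker lists for other cells, 5 had a median in homozygous muscle below the 95% range of random lists. On the log2 scale these medians were -1.30 for nerve and Schwann cells (4 of 4 measured genes at least 2-fold lower), -1.03 for immune cells (3 of 6 lower and 1, Cd3e, higher), -0.81 for fibroblasts (0 of 4), -0.78 for adipocytes (2 of 5) and -0.51 for erythroid cells (0 of 5). Smooth muscle and pericyte genes, at -0.50, and endothelial genes, at -0.41, lay inside that range, with percentiles of 3.27 and 17.3. In heterozygous muscle these 7 lists stood, in the same order, at 0.25, 0.23, 0.38, 0.68, 0.41, -0.15 and 0.15, with adipocyte and erythroid genes above the range of random lists and the others inside it. Cfd, the adipocyte gene with the largest rise in heterozygous muscle, had 1028, 3709 and 725 RPM in wild type, heterozygous and homozygous muscle. Lep, in the same list, was lower in both knock-in libraries, at 47.3, 24.1 and 10.2 RPM. Cardiac muscle genes, of which 4 of 10 were measured and which share Myl2 with slow fibres, stood at -1.58 and -1.70, below that range in both, and fetal muscle genes at -0.14, inside it, and 0.40, above it. Fewer than 3 of the satellite cell markers were measured, so that list has no value.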

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

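Apart from the genotype order of parts, which was planned, the tests in this part were chosen after the results they bear on were seen, and so was the reading given to each. Genes at least 8-fold higher than wild type in both knock-in libraries, with at least 100 reads, were searched outside the splicing comparisons by a rule set after seeing the data, and 5 were found. S100a9, a neutrophil gene, had 0.392 RPM in wild type, 31.7 in heterozygous and 31.2 in homozygous muscle. Ngp, also of neutrophils, had 0 reads in wild type, 10.9 RPM in heterozygous and 13.8 in homozygous muscle, and Camp had 0.0292, 11.8 and 7.87. The bone genes Bglap and Bglap2 had 22.2 and 12.5 RPM in heterozygous and 14.1 and 9.11 in homozygous muscle, with 4 and 2 reads in wild type; they are near-identical copies, so how reads divide between them is uncertain. Ibsp, another bone gene seen early, had 0.0375, 7.60 and 3.52 RPM in the 3 libraries. Bone genes listed before their levels were looked up were not 2-fold higher in both. In heterozygous and homozygous muscle, Alpl was at 0.515-fold and 0.487-fold of wild type on values plus 1 RPM. Smpd3 was at 0.748-fold and 0.287-fold, and Col22a1 at 1.67-fold and 1.01-fold. In wild type, Alpl, Smpd3 and Col22a1 already had 14.1, 5.40 and 7.17 RPM, where Bglap had 0.0167. Their levels therefore do not decide whether bone was present in the knock-in samples. The others with values had under 5 RPM in every library.

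Bone marrow or blood cells in the 2 knock-in samples, carried over with the muscle, are a candidate explanation. Of the marrow genes seen early, S100a8 and Ltf were at least 2-fold higher in both knock-in libraries and Mpo in heterozygous only (6.35-fold, and 1.48-fold in homozygous). In wild type, heterozygous and homozygous, the Retnlg part named above held 0, 91 and 63 inclusion reads and 1360, 801 and 0 exclusion reads. So the inclusion reads of this neutrophil gene's part were higher in both knock-in libraries than in wild type, and its exclusion reads were lower in both. Erythroid genes stood at a median log2 ratio to wild type of 0.41 in heterozygous and -0.51 in homozygous. Of 10 further neutrophil and marrow genes, listed before their levels were looked up but with the pass mark set afterwards, 2 (Elane and Chil3, both under 5 RPM) were at least 2-fold higher in both knock-in libraries, while the 2 that reached 5 RPM, Mmp9 (6.51, 12.0 and 1.11 RPM in wild type, heterozygous and homozygous) and Prtn3 (2.84, 5.43 and 2.11), were not, and the blood cell genes Ptprc (7.65, 12.0 and 2.15) and Lyz2 (230, 265 and 105) were lower in homozygous. For cartilage, tendon or joint tissue in the 2 knock-in samples, which is open as well, of 6 measured genes whose values had not been seen, 3 (Comp, Tnmd and Fmod) were at least 2-fold higher in heterozygous and 1 (Fmod) in homozygous and in both, and of 4 whose values had been seen, Prg4, Chad and Cilp2 were at least 2-fold higher in both, and Col11a2 was 6.03-fold higher in heterozygous and 1.22-fold in homozygous. Neither source can be told apart from a difference of genotype, which is untested with 1 library each.

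The number of parts that differed between homozygous and wild type, 11401, may be asked about in the same way. Counting error alone gave 1172, so it does not account for most of them. The heterozygous library lay between the others in 65.2% of the parts and wild type lay between in 67.8% of its own set, so the number of mutant copies as the cause of most has no support here, but with 1 library per genotype it is not excluded. Differences between animals, muscles sampled and amplification stay open, as no second library of any genotype was used here.

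The Ttn pattern, with some PEVK parts higher in homozygous and others lower in heterozygous muscle, could be technical or biological. No part was in both sets: the 15 higher in homozygous and the 15 lower in heterozygous than in wild type were 30 parts. In the first set heterozygous averaged 33.0% against 37.8% in wild type. In the second set homozygous averaged 33.7% against 28.0% in wild type. The 15 lower parts include the non-coding part at 76935924, lower in homozygous too (51.6%, 26.0% and 25.9% in wild type, heterozygous and homozygous). Exon 171, in the same PEVK stretch, ran the other way in both, at 52.4%, 78.1% and 41.2%. Counting error gave 0 Ttn parts past the rule in every simulation, against these 15 and 15, so it does not account for the pattern. The simulation took each read as a separate molecule, so it does not test amplification. Among the 15 parts higher in homozygous than in wild type, the heterozygous PSI lay between the others in 3 and below both in 12, where the amount of slow-fibre RNA or the number of mutant copies, as the only cause, would put it between. With 1 library per genotype there is no spread between animals to set this against, and neighbouring parts have similar exclusion counts, so neither explanation is excluded. The muscle sampled, the animal and amplification stay open too.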

How the results depend on the processing

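The junction support, 100-read, overlapping-gene and same-exclusion settings were chosen after seeing the data. The other settings were planned, but the Ttn comparison of homozygous against heterozygous was added after the data were seen. No paired analysis was possible because there is 1 library per genotype, and for the same reason no library could be left out. Counts are given in the order homozygous against wild type, heterozygous against wild type, homozygous against heterozygous, with main counts of 11401, 12430 and 11322. They were 19986, 21163 and 19400 at 10 points and 7379, 8081 and 7314 at 30 points. They were 3852, 3890 and 3790 without parts at 0 or 100%, 2069, 2756 and 2221 at 100 reads, 1991, 2602 and 2075 at 100 reads with a supported junction, and 4959, 5265 and 4888 with 1 part per gene. Each of these counts fewer or more parts by construction. The other 8 settings stayed within 1.5 times for each pair.

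Ttn parts numbered 23 in homozygous and 79 in heterozygous against wild type. They were 84 and 154 at 10 points, 0 and 38 at 30 points, and 1 and 1 with 1 part per gene. For heterozygous they were 25 without parts at 0 or 100%, 16 with a supported junction, 16 with that and 100 reads, and 19 with parts of the same exclusion counts taken as 1. The share of higher parts in heterozygous moved from 81.0% to 6.25% with a supported junction. In homozygous it moved from 65.2% to 93.8% with that setting, and to 48.8% (41 higher, 43 lower) at 10 points. In homozygous against heterozygous, added for Ttn after the data were seen, the 116 parts became 188 at 10 points and 65 at 30 points. They became 41 without parts at 0 or 100%, 35 with a supported junction, and 33 with parts of the same exclusion counts taken as 1.

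The RBM20 heart list stood at the 99.99th percentile, at 99.47 by share of parts, at 99.92 with a supported junction, and at 100 with unmatched lists, without Ttn, at 20 reads, or at 100 reads with a supported junction. The share with heterozygous between the others moved from 65.2% to 61.4% at 10 points, 68.6% at 30 points, 38.0% with ends left out, 67.2% with 1 part per gene and 64.1% at 100 reads with a supported junction. In each of these the share with wild type between was higher, at 63.4%, 71.2%, 41.8%, 68.3% and 70.3%. Shared parts moved from 4947 to 9604 at 10 points, 2865 at 30 points and 2692 with 1 part per gene. The cause of these moves was not tested. Many calls rest on few reads, with a median of 35 in the shallower library for homozygous against wild type. In that pair 2069 of 95466 parts with at least 100 reads differed, against 11401 of 204571 with at least 10.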

Other observations

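The settings used in this part were chosen after seeing the data. With at least 100 reads in both libraries and a supported junction, 1991 parts in 1170 genes differed between homozygous and wild-type muscle, 951 higher and 1040 lower. The RBM20 heart targets then had a median largest difference of 15.4 points between homozygous and wild type against 5.06 in matched random lists, a percentile of 100. The value was 17.5 points, also a percentile of 100, between homozygous and heterozygous, and 9.30 points, a percentile of 93.5, between heterozygous and wild type. The contrast is not particular to that list. With percentiles in the order homozygous against wild type, heterozygous against wild type and homozygous against heterozygous, splicing regulators stood at 99.91, 99.88 and 99.99, costamere genes at 99.92, 99.89 and 100, and postnatal splicing genes at 99.22, 99.71 and 99.36. Calcium-handling genes stood at 60.4, 99.21 and 98.31, sarcomere genes at 50.8, 86.7 and 81.3, and glycolysis genes at 38.1, 68.7 and 21.4.

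Of the 1991 parts, 110 had 0 exclusion reads in one library and at least 100 in the other, as Mpc1 did. Prg4, which codes lubricin of joints and tendon sheaths, had 9.75 RPM in wild type, 133 in heterozygous and 75.3 in homozygous muscle. Ucp1, the brown fat uncoupling protein, had 0.0375, 7.70 and 7.25 RPM, and Cidea 2.46, 35.0 and 15.4. None of the other brown fat genes looked up was 2-fold higher. On values plus 1 RPM, Cox7a1 was at 1.01-fold and 0.820-fold of wild type in heterozygous and homozygous, and Cox8b at 1.13 and 0.911. Ppargc1a was at 1.46 and 0.473, and Pparg at 1.33 and 0.366. In wild type, Cox7a1, Cox8b, Ppargc1a and Pparg already had 864, 874, 17.2 and 14.4 RPM. Reads on the scale of Ucp1 could not double such levels. Elovl3 and Dio2 had under 5 RPM in every library. These genes therefore do not decide whether brown fat was present. Prg4, Ucp1 and Cidea were named after their values were seen.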
